A study of Mus musculus with 4 samples.

How the data were processed

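Bulk RNA-seq of the mouse erythroblast line G1E was re-analysed from the authors' deposited tables, 1 for each of the 6 pairs of 4 groups: the G1E control, GATA-1 WT, GATA-1 2RA and GATA-1 V205M. Per the labels, each group is 1 sample, all were treated with β-estradiol, and libraries were made with a TruSeq RNA kit. Per the submitters' processing notes, TopHat, Cufflinks, Cuffdiff, deepTools and the mm10 build were used, without saying which tool made these tables, and versions are not given in the sources used here. The column names resemble those of R's DESeq package, but the tool behind the test is not given in the sources used here.

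The signal in each table is the authors' mean read count of a group after division by a size factor, as the deposited values themselves show. Each level was a whole number of reads times a fixed step, or a sum over 2 such steps, within a tolerance of 3e-11, and whole reads were recovered for 100.0% of the values of each group. The lowest count was 1 in all 6 count columns, with 31 to 57 genes at it, and no value of the 2 groups with 2 count columns was solved by a count of 0 when 0 was allowed. Whether 1 was added to every count or genes with 0 reads were left out is not given in the sources used here. The steps gave size factors of 1.167 and 0.3574 for the 2 count columns of G1E control, 1.588 for GATA-1 WT, 1.4 for GATA-1 2RA, and 1.163 and 0.9983 for the 2 of GATA-1 V205M. The labels name 1 sample where 2 count columns were found, and whether these are cultures or sequencing runs is not given in the sources used here. The folds, intervals and list percentiles of the report do not treat them as replicates. In the authors' mean over both groups, G1E control had a weight of 0.6667 against GATA-1 WT and of 0.5 against GATA-1 V205M. The authors thus entered each count column separately, so the adjusted p-values behind the listed genes may treat these columns as replicates. The edgeR quasi-likelihood fits, used only as alternatives, take their spread from these columns. Common BCVs of 0.0252 to 0.0858 in these fits may therefore be spread between runs of 1 sample. Over genes with 500 or more reads, the SD of the log2 ratio between the 2 columns was 0.130 in G1E control and 0.102 in GATA-1 V205M. The deposited fold is the ratio of the 2 group means, and the deposited log2 value is its logarithm with nothing further added to these means. The authors' p-value comes with a Benjamini-Hochberg adjusted value over 12931 tested genes, and the authors kept genes with an adjusted p-value below 0.01 and a change above 2-fold. Unlisted genes of a pair are therefore known only through other tables.

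The plan written before the data were examined assumed FPKM, while the tables hold scaled read counts, so the same rules were applied to scaled reads. Genes were matched between tables by symbol, and 2731 of 2982 symbols were found in GENCODE M21, from which coordinates on GRCm38 were taken. Log2 changes used a pseudocount of 1 scaled read. Folds printed with an interval are the ratio of the authors' levels, and the 95% interval comes from the pooled recovered reads of each group and covers counting error only. Named genes were, by a rule fixed beforehand, Gata1, Esr1, Zfpm1, Gata2 and Kit; per comparison the 10 listed genes with the largest increase and the 10 with the largest decrease in log2 scaled reads plus 1, among those with 10 or more scaled reads in the higher group and outside the small RNA list; the 4 members of each gene list with the largest change; and the 10 largest genes per mutant that ran opposite to the GATA-1 WT response when set against GATA-1 WT. A few further list members are named where a count is broken down, and 2 genes that the rule selects are not reported here.

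The 25 gene lists covered globins, heme synthesis, iron handling, red cell membrane, other erythroid maturation, erythroid transcription factors, stem and progenitor, megakaryocyte, mast cell, eosinophil and basophil, neutrophil and macrophage, lymphocyte, endothelial, stromal, cell cycle, growth arrest, autophagy, interferon, immediate early and stress, glycolysis and hypoxia, cholesterol and fatty acid, estrogen response, histone, mitochondrially encoded and small RNA genes. For lists with 3 or more listed members, the median log2 change was placed among the medians of 10000 random lists of listed genes of the same size, matched on 10 classes of mean level. This percentile describes these libraries and is no test of the conditions. Counts of higher and lower members cover listed genes only. The remaining members of a list, often the greater part, are not counted. No p-value across genes was computed for a comparison. The histone list was fixed as a gauge of the share of reads without a poly(A) tail, so its counts may not reflect expression alone.

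Sharing between comparisons against the control was set beside the product of the list sizes over 12931 genes and beside simulated unchanged groups that share the control's reads. Simulated genes were called at a 2-fold change and a z above 3.2 that assumed a BCV of 0.05, whatever spread was simulated. Their levels were drawn from the control levels of listed genes. edgeR 4.0.16 in R 4.3.3 was run on the recovered reads as a check of listed genes, by quasi-likelihood fits and by exact tests with an assumed BCV of 0.2 or 0.4. Because listed genes were already selected, these fits are no independent test. On simulated reads for GATA-1 V205M vs G1E control, the quasi-likelihood fit found 96.5% of 200 genes changed 4-fold among 1813, and called 1 unchanged gene. The simulated columns were independent replicates with a wider spread than the fits to the data gave. These rates therefore do not carry over to count columns that may be runs of 1 sample. On 2000 simulated genes for GATA-1 WT vs G1E control, 95.8% of the counting intervals held the true fold. Any simulated gene without control reads was counted as held, and the simulated reads had counting error only. Recovery of reads was tested on 2466 simulated values, and all were solved. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

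The alternatives were a 4-fold threshold, stricter adjusted p-values, filters of 1 and 5 scaled reads, other pseudocounts, centring on the median of all listed genes, leaving out small RNA and histone genes, the edgeR fits, and leaving out 1 of 2 count columns. Because only changes above 2-fold are listed, the median of all listed genes takes the sign of the direction with more genes. It is no measure of a shift between libraries.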

Results

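RNA-seq was done on the mouse erythroblast line G1E, which was derived from cells lacking GATA-1, the zinc finger transcription factor that drives red cell maturation. The labels name 4 groups with 1 sample each: the G1E control, G1E cells with wild-type GATA-1 (GATA-1 WT), and G1E cells with 1 of 2 mutant forms, GATA-1 2RA and GATA-1 V205M. V205M is known to weaken the binding of GATA-1 to its cofactor FOG-1 (Zfpm1), while the labels do not say what 2RA changes. All 4 samples were treated with β-estradiol. The authors' 6 deposited tables compare the groups in pairs and list only genes with an adjusted p below 0.01 and a change above 2-fold, so a gene missing from a table was either below those limits or not tested. The tables hold 2982 genes in all, of 12931 tested, and 1157 of them have a level in each of the 4 groups. Levels are reads divided by a size factor for each library (scaled reads). Summed over the listed genes, the recovered reads came to 1015015 and 276064 in the 2 count columns of G1E control, 2178397 in GATA-1 WT, 1218762 in GATA-1 2RA, and 1147539 and 977544 in the 2 count columns of GATA-1 V205M. There is no replicate check of any difference between groups, because each group is 1 sample.

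Gata1 RNA was lowest in the G1E control, at 153 scaled reads, and stood at 2652 in GATA-1 WT, 1421 in GATA-1 2RA and 614 in GATA-1 V205M. The labels state no order of Gata1 RNA, and a Gata1 level by itself does not tell the wild-type form from a mutant form. Gata1 RNA was 17.4-fold (95% counting interval 14.8 to 19.4) higher in GATA-1 WT than in the control. The level in GATA-1 WT was 4.32-fold (95% counting interval 4.07 to 4.61) that of GATA-1 V205M, and the difference from GATA-1 2RA (-0.90 on the log2 scale) was not listed. Which part of the gene the control's reads came from is not given in the sources used here. In GRCm38, Gata1 lies on chromosome X at 7959260 to 7978071, Gata2 on chromosome 6 at 88193891 to 88207032, Kit on chromosome 5 at 75574916 to 75656722, Esr1 on chromosome 10 at 4611593 to 5005614, Hba-a1 on chromosome 11 at 32283511 to 32284465, Alas2 on chromosome X at 150547375 to 150570638 and Cpa3 on chromosome 3 at 20215620 to 20242181. Esr1, the estrogen receptor gene, ranked the groups as Gata1 did, with 1.83, 58.6, 43.6 and 13.3 scaled reads in G1E control, GATA-1 WT, GATA-1 2RA and GATA-1 V205M. Whether these reads came from the cells' own Esr1 gene or from an introduced construct is not given in the sources used here. A response of the cells' own Esr1 to GATA-1 is therefore not shown. The control value of Esr1 rests on 1 read in each count column, and the ratio of GATA-1 WT to it was 32.0-fold (95% counting interval 12 to 374). No listed gene had 0 reads in any of the 6 count columns, and the lowest count was 1 in each. Whether 1 was added to every count or genes with 0 reads were left out is not given in the sources used here, so a value of 1 read, and any ratio to it, holds for the deposited counts only. Zfpm1 was not listed in any of the 6 tables. Counting intervals here and below cover counting error only, use the pooled reads of a group, and say nothing about the spread between cultures.

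**Figure D1:**
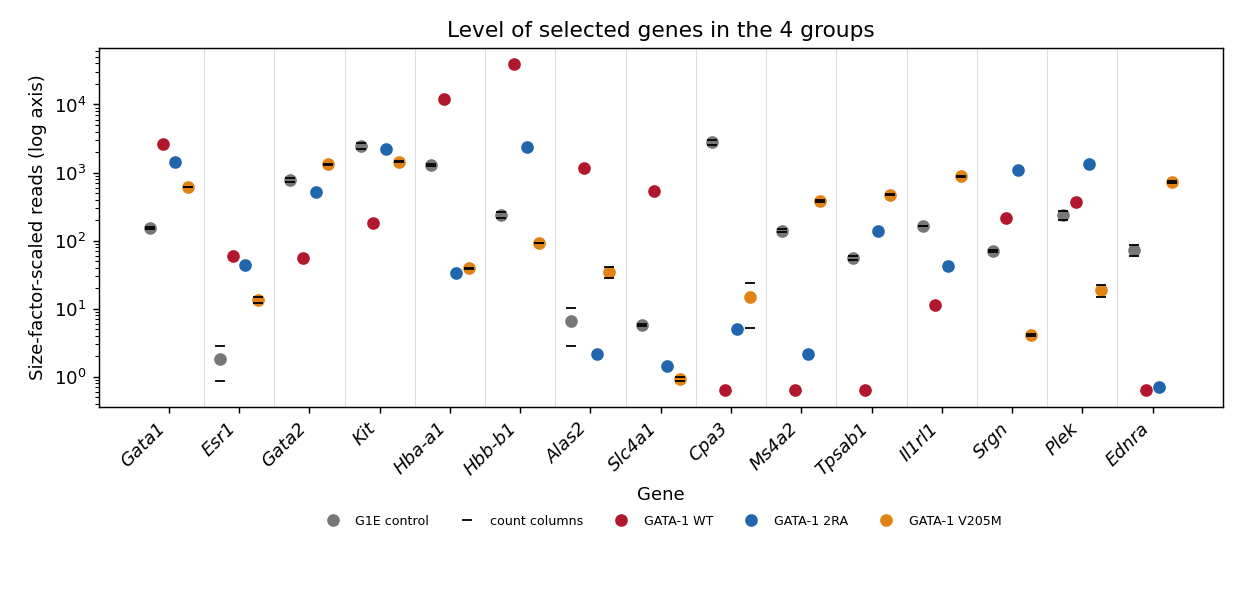
Level of 15 genes in the 4 groups, in size-factor-scaled reads on a log axis, where large points are the authors' group values and short black bars are the 2 count columns of G1E control and of GATA-1 V205M. Hbb-b1 stands at 39108 in GATA-1 WT and 91.6 in GATA-1 V205M, and Kit at 179 in GATA-1 WT against 2429 in the control.

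The comparison of GATA-1 WT with the G1E control asks which genes differ when functional GATA-1 is present. Genes of the red cell program were higher and genes of mast cells and progenitors were lower in GATA-1 WT. Hbb-b1, an adult beta-globin, stood at 39108 scaled reads against 238 (log2 change 7.35), and Hbb-b2 had a log2 change of 6.90. Alas2, the erythroid enzyme that starts heme synthesis, had a change of 7.26, and Slc4a1, the anion exchanger band 3 of the red cell membrane, 6.28. The other genes with the largest increases were Tmem184a (7.33), the glucose transporter Slc2a3 (7.17), the butyrophilin Btn1a1 (6.64), the claudin Cldn13 (6.54), the antiproliferative gene Btg2 (6.51) and the amino acid transporter Slc38a5 (6.28). Cpa3, the mast cell carboxypeptidase, was lower by the widest margin, with 1 read in GATA-1 WT and 2795 scaled reads in the control, a ratio of 4438-fold (95% counting interval 832 to 183146). Next came Soat1, an enzyme of cholesterol esterification (-7.36), the steroid side-chain cleavage enzyme Cyp11a1 (-7.10), Ms4a2, the beta chain of the high-affinity IgE receptor (-6.43), Tmem44 (-6.25), Slc45a3 (-6.24), the zinc transporter Slc30a2 (-6.03), granzyme B (Gzmb, -5.78), Cited1 (-5.74) and the leukotriene enzyme Alox5 (-5.72). Several of the genes named here rest on 1 to 3 reads in either group, and their ratios of the higher to the lower group, with 95% counting intervals, were Btn1a1 154-fold (58.9 to 1774), Slc38a5 112-fold (43.5 to 624), Soat1 423-fold (77.3 to 17150.2), Cyp11a1 354-fold (63.7 to 14148), Ms4a2 222-fold (40.3 to 9007), Tmem44 116-fold (40.9 to 587), Slc45a3 194-fold (38.5 to 8595), Gzmb 141-fold (23.9 to 5387), Cited1 137-fold (22.8 to 5141) and Alox5 80.3-fold (28.5 to 412).

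Of 25 gene lists fixed before the data were examined, the globin list was higher in GATA-1 WT for all 5 listed members (median log2 change 5.45, percentile 100 of the random lists), led by Hbb-b1 (7.35), Hbb-b2 (6.90), Hba-a2 (5.45) and Hbb-bh1 (4.0). Hba-a1 and Hba-a2, like Hbb-b1 and Hbb-b2, are near-identical copies, so the split of reads between them is uncertain. All 11 listed genes of heme synthesis were higher (median log2 change 2.25, percentile 99.4 of the random lists), with Alas2 (7.26), Abcb10 (5.14), Slc25a38 (3.67) and Uros (2.60) changed most. The red cell membrane list had 16 higher and 0 lower (median log2 change 2.52, percentile 100 of the random lists), led by Slc4a1 (6.28), Spnb1 (3.94) and Epb4.9 (3.40), where Spnb1 encodes beta-spectrin. Other erythroid maturation genes were 14 higher and 1 lower (median log2 change 2.27, percentile 99.9 of the random lists), led by Btg2 (6.51), Slc38a5 (6.28), Ube2l6 (4.92) and Hebp1 (4.33). Erythroid transcription factors and cofactors were 10 higher and 2 lower (median log2 change 1.59, percentile 88.4 of the random lists), led by Gata1 (4.11), Lmo2 (3.96), Bach1 (3.64) and Mafk (2.85). Gata1 is the introduced gene, so its rise against the control follows from the design. Wherever Gata1 is listed, the counts, medians and percentiles of this gene list include it. The stem and progenitor list had 2 higher and 8 lower (median log2 change -2.95, percentile 0 of the random lists), with Vim (-5.11), Ikzf2 (-4.01), Gata2 (-3.79) and Kit (-3.76). Gata2, the GATA factor of progenitors, stood at 773 scaled reads in the control and 54.8 in GATA-1 WT, and Kit, the stem cell factor receptor, at 2429 and 179. Mast cell genes were 1 higher and 11 lower (median log2 change -5.39, percentile 0 of the random lists), the exception being serglycin (Srgn, 1.61). Megakaryocyte genes were 2 higher and 2 lower (median log2 change -0.49, percentile 47.5 of the random lists): Tubb1 (4.51), P2rx1 (-3.68), Nbeal2 (-2.25) and Fli1 (1.27). With 1 to 3 reads in either group, the ratios and 95% counting intervals were Hbb-bh1 22.6-fold (8.56 to 128) and Tubb1 34.8-fold (13.1 to 406).

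Glycolysis and hypoxia genes were higher in GATA-1 WT for all 16 listed members (median log2 change 2.02, percentile 99.2 of the random lists), led by Slc2a3 (7.17), Bnip3 (4.37), Pfkm (3.50) and P4ha1 (3.18). Iron handling genes were 5 higher and 1 lower (median log2 change 1.77, percentile 83.9 of the random lists), with Blvrb (3.19), Slc25a37 (2.40), Fth1 (-2.22) and Tfrc (1.81), where Fth1 is the ferritin heavy chain and Tfrc the transferrin receptor. Cell cycle genes were 19 higher and 3 lower (median log2 change 1.67, percentile 95 of the random lists), with Cdc25b (3.27), Ccne1 (2.82), Ccna2 (2.55) and Cdc6 (2.52). Growth arrest genes were 7 higher and 0 lower (median log2 change 2.34, percentile 99.7 of the random lists), with Btg2 (6.51), Ccng2 (2.81), Cdkn1b (2.77) and Gadd45g (2.34). Autophagy genes were 6 higher and 0 lower (median log2 change 1.67, percentile 83.1 of the random lists), with Bnip3 (4.37) and Atg4d (2.49). Immediate early and stress genes were 8 higher and 0 lower (median log2 change 2.02, percentile 98.5 of the random lists), with Txnip (3.82) and Ddit3 (2.79). Cholesterol and fatty acid genes were 2 higher and 5 lower (median log2 change -1.31, percentile 1.2 of the random lists), with Elovl6 (-2.61), Dhcr7 (-1.83), Fasn (-1.36) and Sc5d (-1.31). All 7 listed mitochondrially encoded genes were lower (median log2 change -1.63, percentile 0.1 of the random lists), with mt-Nd1 (-1.97) and mt-Nd4 (-1.86), and 6 replication-dependent histone genes were higher (median log2 change 1.45, percentile 53.7 of the random lists), with Hist1h1c (2.57) and Hist1h1e (1.60). No gene of the lymphocyte list was listed in any of the 6 tables. Across the 6 tables the endothelial list gave 1 gene (Egfl7), the stromal list 1 (Col5a1), the small RNA list 1 (Scarna13), and the eosinophil and basophil (Cd200r3, Il4), neutrophil and macrophage (Csf2rb, Itgb2), interferon (Ifit2, Usp18) and estrogen response (Ccnd1, Esr1) lists 2 each.

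The authors' deposited table lists 1685 genes for this comparison, 1057 higher and 628 lower in GATA-1 WT. Testing the reads compares these libraries, not the conditions: with a spread between cultures assumed at a biological coefficient of variation (BCV) of 0.2, 609 higher and 379 lower genes passed, and with 0.4, 60 and 46.

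**Figure D2:**
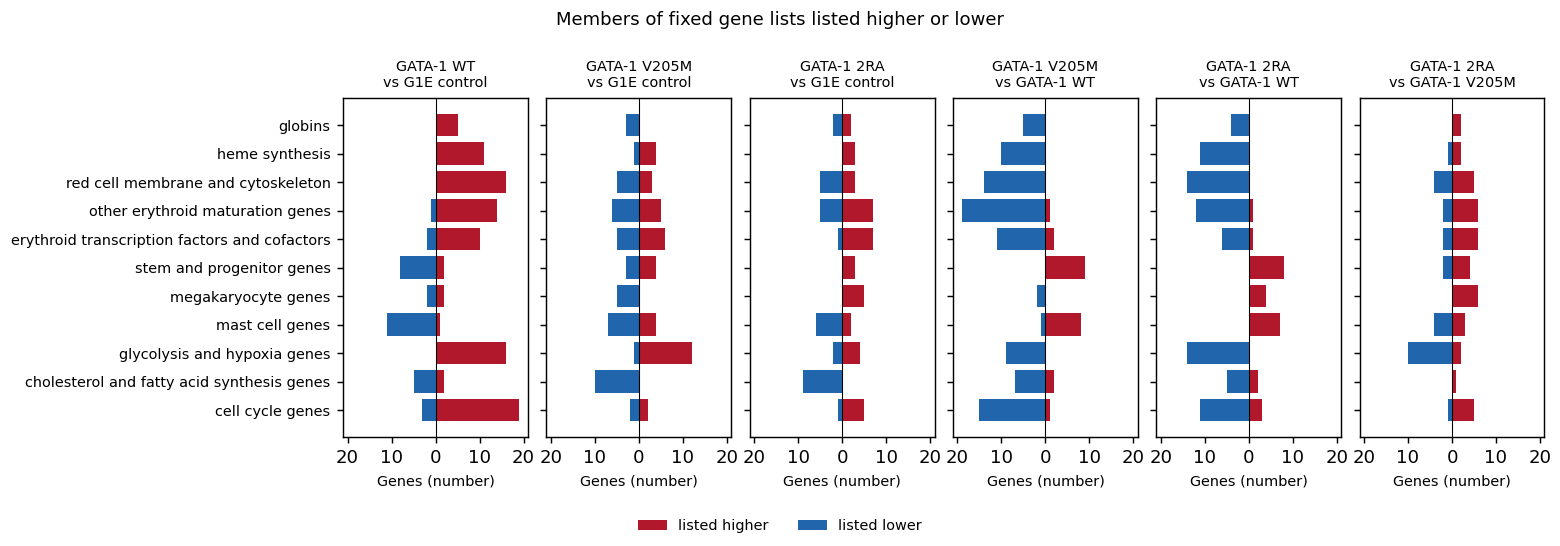
Number of members of 11 fixed gene lists that each of the 6 authors' tables lists as higher (red, right) or lower (blue, left) in the group named first. In GATA-1 WT vs G1E control 16 red cell membrane genes point right, and in both mutants vs GATA-1 WT 14 point left.

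GATA-1 V205M against the G1E control asks which genes differ with the form whose FOG-1 binding is weakened. No globin was higher, 3 were lower, and mast cell genes went both ways. The largest increases were those of the connexin gene Gja6 (6.43), the decarboxylase Ddc (5.64), Mboat2 (5.49), the lysosomal protease legumain (Lgmn, 5.16), the sialic acid hydroxylase Cmah (4.67), 1700042O10Rik (4.56), Jub (4.55), Gdf9 (4.50), the phosphofructokinase Pfkm (4.37) and Cldn13 (4.02). On chromosome 11, 1700042O10Rik (11868123 to 11885321) lies within Ddc (11814101 to 11898144) on the opposite strand. The split of reads between them is therefore uncertain, here and below. Cpa3 was again the gene lower by most (-7.49), followed by Rgs13 (-5.42), galectin-1 (Lgals1, -5.39), Pklr, the pyruvate kinase of liver and red cells (-5.18), the death ligand Tnfsf10 (-5.11), Fgf15 (-5.02), Hba-a1 (-5.01), Gzmb (-4.93), Cited1 (-4.93) and Rhag, the Rh-associated glycoprotein (-4.78). Hba-a1 stood at 38.9 scaled reads in GATA-1 V205M against 1291 in the control. Where either group had 1 to 3 reads, the ratios of the higher to the lower group, with 95% counting intervals, were Gja6 133-fold (51.0 to 1533), Cmah 38.7-fold (14.8 to 452), Gdf9 34.4-fold (13.0 to 400.0), Rgs13 87.9-fold (23.6 to 728) and Tnfsf10 57.9-fold (19.1 to 281).

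Gata2 (0.77) and Kit (-0.75) were not listed in this comparison. Mast cell genes were 4 higher and 7 lower (median log2 change -1.95, percentile 0.1 of the random lists). The 4 higher were the tryptase Tpsab1 (3.08), the IL-33 receptor Il1rl1 (2.43), the histamine-forming enzyme Hdc (2.00) and Ms4a2 (1.45). All 5 listed megakaryocyte genes were lower (median log2 change -2.62, percentile 3.6 of the random lists), with Plek (-3.59), Rab27b (-2.95), P2rx1 (-2.62) and Gp5 (-2.13). The other 24 of the 29 genes on that list were not listed. Stem and progenitor genes were 4 higher and 3 lower (median log2 change 1.59, percentile 95.8 of the random lists), with Lyl1 (-3.74), Csf2rb (3.58), Csf2rb2 (2.08) and Lmo4 (-1.88); Csf2rb and Csf2rb2 are near-identical copies. Globins were 0 higher and 3 lower (median log2 change -1.58, percentile 14.8 of the random lists), with Hba-a1 (-5.01), Hba-a2 (-1.58) and Hbb-b1 (-1.37). Heme synthesis genes were 4 higher and 1 lower (median log2 change 1.59, percentile 92.1 of the random lists), with Alas2 (2.24), Tmem14c (1.75), Alad (-1.62) and Abcb10 (1.59). Red cell membrane genes were 3 higher and 5 lower (median log2 change -1.30, percentile 7.4 of the random lists), with Rhag (-4.78), Epb4.2 (-2.92), Spnb1 (2.86) and Spna1 (-2.55). Other erythroid maturation genes were 5 higher and 6 lower (median log2 change -1.59, percentile 0.5 of the random lists), with Pklr (-5.18), Btg2 (3.83), Tspo2 (-3.27) and Acp5 (2.58). Erythroid transcription factors were 6 higher and 5 lower (median log2 change 1.15, percentile 43.1 of the random lists), with Bach1 (3.48), Tal1 (-2.49), Klf3 (-2.36) and Lmo2 (2.27). Glycolysis genes were 12 higher and 1 lower (median log2 change 1.60, percentile 99.4 of the random lists), with Pklr (-5.18), Pfkm (4.37), Slc2a3 (3.43) and Hk2 (2.96). All 10 listed cholesterol and fatty acid genes were lower (median log2 change -1.53, percentile 0.3 of the random lists), with Fads2 (-2.26), Fdft1 (-2.23), Fads1 (-1.80) and Fdps (-1.78). Iron handling genes were 3 higher and 2 lower (median log2 change 1.01, percentile 11.1 of the random lists), with Steap3 (-1.73) and Tfrc (1.59). Their median turned from 1.01 to -0.10 once changes were centred on the median of all listed genes. That centring value follows from the 2-fold filter and measures no shift between libraries. Mitochondrially encoded genes were 0 higher and 4 lower (median log2 change -1.41, percentile 0.4 of the random lists), with mt-Nd2 (-1.63) and mt-Nd4 (-1.46).

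In GATA-1 V205M against the control, cell cycle genes were 2 higher and 2 lower (median log2 change -0.15, percentile 11.9 of the random lists), with Ccnd3 (-2.41) and Ccna2 (1.53). Growth arrest genes were 2 higher and 1 lower (median log2 change 1.72, percentile 93.9 of the random lists), with Btg2 (3.83) and Mxd1 (1.72). Immediate early and stress genes were 3 higher and 1 lower (median log2 change 1.77, percentile 93.1 of the random lists), with Zfp36 (-2.59) and Txnip (2.04). Replication-dependent histone genes were 0 higher and 3 lower (median log2 change -1.17, percentile 8.8 of the random lists), with Hist1h3b (-1.20) and Hist1h3c (-1.17).

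The authors' deposited table lists 1054 genes here, 625 higher and 429 lower in GATA-1 V205M. With an assumed BCV of 0.2 the counts were 234 and 241, and with 0.4 they were 11 and 18.

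In GATA-1 2RA against the G1E control, beta-globin was higher while alpha-globin was lower, and the listed megakaryocyte genes were higher. Hbb-b1 had 2342 scaled reads (3.29), and Hba-a1 32.9 (-5.25). The largest increases were those of Slc2a3 (7.29), Fgl2 (6.37), Tmem184a (6.07), the B-cell adaptor Blnk (5.36), Hoxc10 (5.22), Plekho2 (4.93), Tsc22d1 (4.77), Fermt3, which activates integrins in blood cells (4.77), the G protein subunit Gnb4 (4.70) and Nckap1l, a regulator of actin in blood cells (4.54). Lower by most were Cpa3 (-8.86), Pklr (-6.90), Cyp11a1 (-6.53), Ston2 (-6.29), Gzmb (-5.71), Fgf15 (-5.60), Rgs13 (-5.59), Ms4a2 (-5.49), Gm17004 (-5.42) and the endothelin receptor Ednra (-5.42). The ratios of the higher to the lower group for genes with 1 to 3 reads in either, with 95% counting intervals, were Fgl2 128-fold (48.8 to 1472), Blnk 62.9-fold (23.9 to 730.3), Hoxc10 57.1-fold (21.6 to 663), Pklr 285-fold (51.5 to 11457), Cyp11a1 156-fold (43.2 to 1305), Ston2 186-fold (35.0 to 7831), Gzmb 124-fold (21.1 to 4749), Rgs13 114-fold (19.9 to 4496), Ms4a2 65.3-fold (22.5 to 326) and Ednra 101-fold (19.6 to 4423).

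All 5 listed megakaryocyte genes were higher (median log2 change 2.47, percentile 98.1 of the random lists), with Itgb3 (3.35), Fli1 (3.15), Plek (2.47) and P2rx1 (1.98). The other 24 of the 29 genes on that list were not listed. Stem and progenitor genes were 3 higher and 0 lower (median log2 change 3.87, percentile 99.3 of the random lists), namely Meis1 (4.08), Csf2rb (3.87) and Csf2rb2 (3.78). Csf2rb and Csf2rb2 are near-identical copies and not independent members, so this median and percentile rest largely on them. The other 28 of the 31 genes on the stem and progenitor list were not listed. Gata2 (-0.59) and Kit (-0.13) were not listed. Mast cell genes were 2 higher and 6 lower (median log2 change -5.54, percentile 0 of the random lists), the higher being Srgn (3.93) and Tpsab1 (1.32). Erythroid transcription factors were 7 higher and 1 lower (median log2 change 1.77, percentile 96 of the random lists), with Bach1 (3.26), Gata1 (3.21), Lmo2 (3.06) and Mafk (2.23). Globins were 2 higher and 2 lower (median log2 change -0.40, percentile 19.2 of the random lists), with Hba-a1 (-5.25), Hbb-b1 (3.29), Hba-a2 (-2.76) and Hbb-b2 (1.96). Heme synthesis genes were 3 higher and 0 lower (median log2 change 1.66, percentile 83.1 of the random lists), with Abcb10 (3.22), Tmem14c (1.66) and Slc25a38 (1.15), and Alas2 was not listed (-1.26). Red cell membrane genes were 3 higher and 5 lower (median log2 change -1.16, percentile 6.8 of the random lists), with Add2 (-4.47), Spnb1 (4.09), Rhag (-3.79) and Spna1 (-1.85), where Add2 is beta-adducin. Other erythroid maturation genes were 7 higher and 5 lower (median log2 change 1.37, percentile 76.6 of the random lists), with Pklr (-6.90), Car1 (-4.77), Ube2l6 (4.28) and Btg2 (3.78). Glycolysis genes were 4 higher and 2 lower (median log2 change 1.56, percentile 78 of the random lists), with Slc2a3 (7.29), Pklr (-6.90), Pdk1 (-2.49) and Pfkm (2.04). All 9 listed cholesterol and fatty acid genes were lower (median log2 change -1.75, percentile 0 of the random lists), with Fads2 (-2.25), Scd2 (-2.11), Fads1 (-1.92) and Elovl6 (-1.79). Iron handling genes were 1 higher and 3 lower (median log2 change -1.43, percentile 1.2 of the random lists), with Fth1 (-2.50) and Slc40a1 (-1.61). Immediate early genes were 4 higher and 0 lower (median log2 change 2.63, percentile 98.7 of the random lists), with Jun (4.23) and Txnip (3.06).

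Growth arrest genes in GATA-1 2RA against the control were 6 higher and 1 lower (median log2 change 1.34, percentile 64.9 of the random lists), with Btg2 (3.78) and Gadd45g (2.06). Cell cycle genes were 5 higher and 1 lower (median log2 change 1.49, percentile 73.4 of the random lists), with Ccnd1 (3.75) and Cdc25b (2.09). Mitochondrially encoded genes were 0 higher and 3 lower (median log2 change -1.09, percentile 17 of the random lists), with mt-Rnr1 (-1.90) and mt-Nd2 (-1.09). Replication-dependent histone genes were 0 higher and 3 lower (median log2 change -1.11, percentile 17.4 of the random lists), with Hist1h4h (-1.14) and Hist1h4k (-1.11).

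The authors' deposited table lists 965 genes for this comparison, 628 higher and 337 lower in GATA-1 2RA. An assumed BCV of 0.2 left 268 and 149, and one of 0.4 left 31 and 28.

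Genes listed against the control were in part shared between the forms. GATA-1 WT and GATA-1 V205M had 561 genes in common, 334 higher in both, 187 lower in both and 40 in opposite directions. GATA-1 WT and GATA-1 2RA shared 354 higher and 165 lower, with 29 opposite. The mutants shared 249 higher and 133 lower, with 39 opposite. All 3 tables listed 259 genes the same way, 176 higher and 83 lower. Independent lists of these sizes among the 12931 tested genes would share 51.1 higher and 20.8 lower genes for GATA-1 WT and GATA-1 V205M, 51.3 and 16.4 for GATA-1 WT and GATA-1 2RA, and 30.4 and 11.2 for the mutants. The control library is common to all 3, so part of the excess may come from it. Simulated unchanged groups set against a shared control gave 1, 0 and 0 genes in the same direction for these pairs at a BCV of 0.05, and 35, 52 and 43 at 0.2. At 0.4 they gave 944, 931 and 946, more than was observed, although they then also called between 2717 and 2817 genes per group, more than any authors' table lists. The rule that called simulated genes assumed a BCV of 0.05 throughout, so the counts at 0.2 and 0.4 follow in part from that rule. Simulated levels came only from listed genes. The simulation therefore cannot show how much of the sharing comes from the control.

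The 1057 genes higher and 628 lower in GATA-1 WT than in the control were followed in the mutants. In GATA-1 V205M, 334 of the higher genes (31.6%) were also listed higher against the control, and 472 (44.7%) were listed lower than in GATA-1 WT. In GATA-1 2RA these counts were 354 (33.5%) and 332 (31.4%). Of the 628 lower genes, 187 (29.8%) were also lower in GATA-1 V205M and 165 (26.3%) in GATA-1 2RA, while 236 (37.6%) and 209 (33.3%) were higher there than in GATA-1 WT. These shares overlap, and many genes were listed in neither way. For the higher genes these were 320 (30.3%) in GATA-1 V205M and 426 (40.3%) in GATA-1 2RA. For the lower genes they were 229 (36.5%) and 274 (43.6%). The genes of this kind with the largest distance from GATA-1 WT were Ednra, Hbb-b1, Hba-a1, Tpsab1, Slc4a1, Ms4a2, Hbb-b2, Hba-a2, Col18a1 and Il1rl1 in GATA-1 V205M, and Alas2, Hba-a1, Hba-a2, Npl, Slc4a1, Add2, Cited1, Slc38a5, Ndufa4l2 and Ahnak in GATA-1 2RA. Of the higher genes, 161 were listed lower than in GATA-1 WT in both mutants and higher than the control in neither. Another 118 were listed higher than the control in both mutants and below GATA-1 WT in neither. These counts were not tested, since each group is 1 sample and the comparisons share libraries. GATA-1 V205M also entered the authors' tests as 2 count columns and GATA-1 2RA as 1. Their tables against GATA-1 WT list 1210 and 954 genes, so a difference between the mutants' shares may come from this unequal input.

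**Figure D3:**
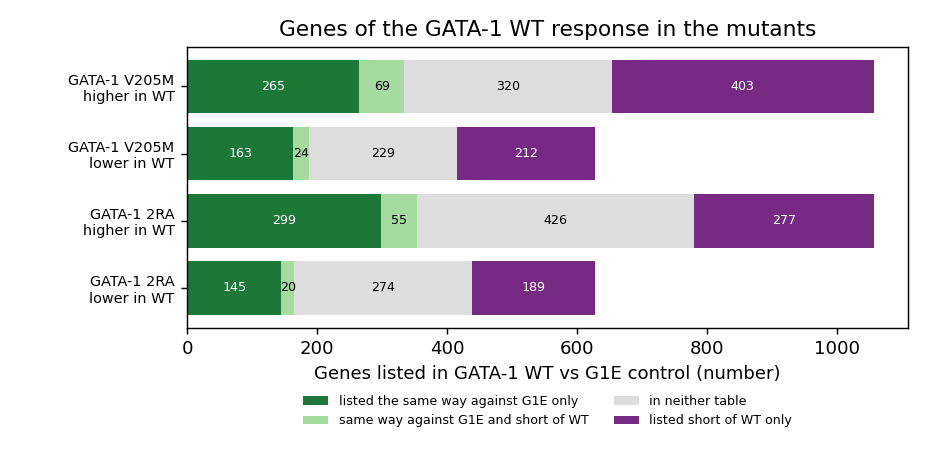
Number of genes listed in GATA-1 WT vs G1E control, by direction, split by how each mutant's tables list them: the same way against the control only (dark green), the same way and also short of GATA-1 WT (light green), in neither way (grey), or short of GATA-1 WT only (purple). For the higher genes the purple part is 403 in GATA-1 V205M and 277 in GATA-1 2RA. GATA-1 V205M rests on 2 count columns and GATA-1 2RA on 1.

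Set directly against GATA-1 WT, GATA-1 V205M had lower globin, heme and membrane genes and higher mast cell and progenitor genes. Hbb-b1 was lower by 427-fold (95% counting interval 371 to 493), Hba-a1 by 308-fold (95% counting interval 249 to 387), and the other genes lower by most were Slc4a1 (-8.09), Hbb-b2 (-7.75), Hba-a2 (-7.03), the collagen Col18a1 (-6.44), Pklr (-5.96), Ndufa4l2 (-5.76), Rhag (-5.68) and Gm3604 (-5.66). Ednra was higher by most, at 729.6 scaled reads against 1 read in GATA-1 WT, a ratio of 1158-fold (95% counting interval 207 to 45631). Tpsab1 (8.19), Ms4a2 (7.88), Ddc (7.05), Il1rl1 (6.16), the sialic acid lyase Npl (6.09), Ahnak (5.98), Plekhg3 (5.89), 1700042O10Rik (5.73) and the proton-sensing receptor Gpr65 (5.70) followed. With 1 to 3 reads in either group, the following had ratios of higher to lower, with 95% counting intervals, of: Slc4a1 566-fold (157 to 4707), Gm3604 104-fold (28.4 to 868), Tpsab1 753-fold (135 to 29792), Ms4a2 608-fold (108 to 23961), Npl 175-fold (31.2 to 6962), Plekhg3 152-fold (27.0 to 6034), 1700042O10Rik 94.7-fold (26.1 to 789.5) and Gpr65 132-fold (23.7 to 5308).

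All 5 listed globins, 10 heme synthesis genes and 14 red cell membrane genes were lower, with none of these higher (median log2 changes -7.75, -2.72 and -3.32, each at percentile 0 of the random lists). The heme list was led by Alas2 (-5.02), Alad (-3.56) and Abcb10 (-3.55) and the membrane list by Slc4a1 (-8.09), Rhag (-5.68) and Epb4.9 (-4.93). Other erythroid maturation genes were 1 higher and 19 lower (median log2 change -1.87, percentile 0.1 of the random lists), with Pklr (-5.96), Slc38a5 (-5.12), Hemgn (-4.6) and Fam46c (-3.03). Erythroid transcription factors were 2 higher and 11 lower (median log2 change -1.69, percentile 2.6 of the random lists), with Klf3 (-2.34), Nfe2 (-2.27), Gata1 (-2.11) and Mllt3 (-1.99). All 9 listed stem and progenitor genes were higher (median log2 change 2.32, percentile 99.9 of the random lists), with Gata2 (4.56), Ikzf2 (4.13), Vim (3.36) and Kit (3.0). Mast cell genes were 8 higher and 1 lower (median log2 change 3.78, percentile 100 of the random lists), with Tpsab1 (8.19), Ms4a2 (7.88), Il1rl1 (6.16) and Hdc (5.40). Cell cycle genes were 1 higher and 15 lower (median log2 change -1.64, percentile 2.2 of the random lists), with Ccnd3 (-4.71), Cdc25b (-2.52), Ccnd2 (2.40) and Kif20a (-1.91). Growth arrest genes were 0 higher and 7 lower (median log2 change -2.04, percentile 0.9 of the random lists), with Btg2 (-2.68) and Ccng2 (-2.49). Glycolysis genes were 0 higher and 9 lower (median log2 change -2.77, percentile 0 of the random lists), with Pklr (-5.96), Slc2a3 (-3.74), Aldoc (-3.71) and Pfkfb4 (-3.0). Replication-dependent histone genes were 0 higher and 25 lower (median log2 change -1.22, percentile 48.8 of the random lists), with Hist1h1c (-2.20) and Hist1h3b (-1.66), but these families share reads between near-identical copies. The list was also fixed as a gauge of reads without a poly(A) tail, so a difference in library preparation was not separated from expression. Megakaryocyte genes were 0 higher and 2 lower, Tubb1 (-5.07) and Plek (-4.23). Autophagy genes were 0 higher and 5 lower (median log2 change -1.21, percentile 47 of the random lists), with Bnip3 (-2.77) and Bnip3l (-1.92). Immediate early and stress genes were 0 higher and 5 lower (median log2 change -1.78, percentile 3.7 of the random lists), with Dusp1 (-2.58) and Klf6 (-1.93), and iron handling genes 1 higher and 5 lower (median log2 change -1.65, percentile 14.1 of the random lists), with Slc25a37 (-3.03) and Blvrb (-2.19). Cholesterol and fatty acid genes were 2 higher and 7 lower (median log2 change -1.42, percentile 16.2 of the random lists), with Scd2 (-2.53) and Fdps (-2.00). Centred on the median of all listed genes, the medians of the histone and autophagy lists were -0.06 and -0.06. Every listed member of both lists was lower, and the centring value follows from the 2-fold filter. The ratios and 95% counting intervals for genes here with 1 to 3 reads in either group were Hdc 64.0-fold (21.5 to 311), Aldoc 21.6-fold (7.18 to 112) and Tubb1 68.4-fold (18.6 to 576).

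The authors' deposited table lists 1210 genes, 479 higher and 731 lower in GATA-1 V205M. At an assumed BCV of 0.2, 218 and 385 passed, and at 0.4, 36 and 47.

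GATA-1 2RA against GATA-1 WT gave the same direction for globin, membrane and progenitor genes as GATA-1 V205M did. Alas2 was lowest relative to GATA-1 WT, with 3 reads in GATA-1 2RA and a ratio of 538-fold (95% counting interval 184 to 2613). It was followed by Hba-a1 (-8.47), Hba-a2 (-8.21), Slc4a1 (-7.76), Pklr (-7.68), Add2 (-7.45), Slc38a5 (-7.21), Ndufa4l2 (-6.53) and the manganese transporter Slc30a10 (-6.35). Hbb-b1 was lower by less, 16.7-fold (95% counting interval 16.1 to 17.3). The largest increases were those of Npl, with 1 read in GATA-1 WT and a ratio of 632-fold (95% counting interval 113 to 24999.7), Cited1 (7.31), Ahnak (6.52), Slc45a3 (6.51), Plekhg3 (6.48), Tpsab1 (6.43), Blnk (6.15), the phosphatase Dusp3 (6.11), Fgl2 (5.82) and P2rx1 (5.66). Ratios of the higher to the lower group, with 95% counting intervals, for the genes with 1 to 3 reads in either were Slc4a1 368-fold (102 to 3048), Pklr 490.2-fold (87.6 to 19395), Slc38a5 353-fold (62.9 to 13963), Ndufa4l2 220.4-fold (39.2 to 8739.6), Cited1 408-fold (72.8 to 16173), Slc45a3 235-fold (41.7 to 9318), Plekhg3 229-fold (40.7 to 9094), Tpsab1 221-fold (39.2 to 8781), Blnk 183-fold (32.3 to 7258) and Dusp3 123-fold (33.7 to 1023).

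Here 4 globins (median log2 change -6.57, percentile 0 of the random lists), 11 heme synthesis genes and 14 membrane genes were lower and none of these lists had a higher member. The heme list (median log2 change -1.44, percentile 8.6 of the random lists) was led by Alas2 (-8.52), Slc25a38 (-2.52) and Uros (-2.35), and the membrane list (median log2 change -2.76, percentile 0 of the random lists) by Slc4a1 (-7.76), Add2 (-7.45) and Rhag (-4.69). Stem and progenitor genes were higher for all 8 listed members (median log2 change 3.29, percentile 100 of the random lists), with Vim (4.58), Meis1 (3.90), Kit (3.62) and Ikzf2 (3.38), and Gata2 had a change of 3.21. All 4 listed megakaryocyte genes were higher (median log2 change 1.94, percentile 95.6 of the random lists), with P2rx1 (5.66), Nbeal2 (2.01), Fli1 (1.88) and Plek (1.84). The other 25 of the 29 genes on that list were not listed. All 7 listed mast cell genes were higher too (median log2 change 3.58, percentile 99.6 of the random lists), with Tpsab1 (6.43), Alox5 (5.56), Kit (3.62) and Hdc (3.58). Other erythroid maturation genes were 1 higher and 12 lower (median log2 change -2.59, percentile 0 of the random lists), with Pklr (-7.68), Slc38a5 (-7.21), Trim10 (-4.92) and Car1 (-4.26). Erythroid transcription factors were 1 higher and 6 lower (median log2 change -1.46, percentile 8.8 of the random lists), with Tfdp2 (-2.06), Stat5a (2.05), Klf1 (-1.89) and Gfi1b (-1.74). Glycolysis genes were lower for all 14 listed members (median log2 change -1.87, percentile 0 of the random lists), with Pklr (-7.68), Bnip3 (-4.58), Pdk1 (-3.39) and Ldha (-2.26). Cell cycle genes were 3 higher and 11 lower (median log2 change -1.26, percentile 22.1 of the random lists), with Ccnd1 (5.08), Ccne1 (-3.57), Cdk6 (2.41) and Ccnd2 (2.34). Growth arrest genes were 0 higher and 4 lower (median log2 change -2.42, percentile 1.3 of the random lists), with Btg2 (-2.74) and Gadd45a (-2.71), and iron handling genes 0 higher and 4 lower (median log2 change -1.92, percentile 2.3 of the random lists), with Blvrb (-2.41) and Slc25a37 (-2.21). Replication-dependent histone genes were 0 higher and 24 lower (median log2 change -1.19, percentile 52.2 of the random lists), with Hist1h1c (-2.93) and Hist1h1d (-2.12). Here too, library preparation was not separated from expression. Mitochondrially encoded genes were 2 higher and 0 lower, with mt-Tp (2.40) and mt-Nd1 (1.47). Autophagy genes were 0 higher and 3 lower (median log2 change -2.28, percentile 2.1 of the random lists), with Bnip3 (-4.58) and Bnip3l (-2.28). Cholesterol and fatty acid genes were 2 higher and 5 lower (median log2 change -1.39, percentile 14.8 of the random lists), with Insig1 (4.75) and Scd2 (-3.15). In these lists the genes with 1 to 3 reads in either group had ratios and 95% counting intervals of: Alox5 71.8-fold (24.2 to 352), Hdc 17.8-fold (5.72 to 89.3), Trim10 43.8-fold (14.7 to 215), Ccnd1 86.2-fold (15 to 3449) and Insig1 68.1-fold (11.8 to 2732).

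The authors' deposited table lists 954 genes, 431 higher and 523 lower in GATA-1 2RA. How many of them passed at assumed BCVs of 0.2 and 0.4 is given below. An edgeR fit of these 2 groups alone with an estimated spread was not run, because both have 1 count column. The joint fit over all groups, described below, took its spread from the count columns of the other groups.

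Between the mutants, the listed megakaryocyte genes were higher in GATA-1 2RA, most listed glycolysis genes were higher in GATA-1 V205M, and several mast cell genes separated them. Col18a1 (7.71) and Srgn (7.71) were higher in GATA-1 2RA by most, with Srgn at 1077 scaled reads against 4.15. Fgl2 (6.59), Cited1 (6.50), Plek (6.07), Blnk (5.91), Gnb4 (5.71), Gm3604 (5.56), Agpat3 (5.39) and the carboxypeptidase Cpz (5.39) came next. Ednra had 1 read in GATA-1 2RA and was 1021-fold (95% counting interval 182 to 40227) lower there. Mboat2 (-7.45), Ddc (-7.21), Ms4a2 (-6.93), Ggta1 (-6.06), Gja6 (-5.98), 1700042O10Rik (-5.63), Cmah (-5.39), the splicing factor Rbfox2 (-5.27) and Ehf (-5.14) were also lower in GATA-1 2RA. Among these, genes with 1 to 3 reads in either mutant had ratios, with 95% counting intervals, of: Fgl2 163-fold (56.9 to 818), Blnk 124-fold (33.9 to 1035), Gm3604 96.7-fold (26.4 to 812), Agpat3 86.0-fold (23.4 to 723), Mboat2 418-fold (75.0 to 16597), Ddc 217-fold (74.2 to 1057), Ms4a2 179-fold (60.7 to 865), Ggta1 159-fold (28.2 to 6291), 1700042O10Rik 83.5-fold (23.0 to 696), Cmah 99.0-fold (17.6 to 3964) and Ehf 83.1-fold (14.8 to 3349.8).

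All 6 listed megakaryocyte genes were higher in GATA-1 2RA (median log2 change 2.99, percentile 99.6 of the random lists), with Plek (6.07), P2rx1 (4.6), Gp5 (3.22) and Fli1 (2.77). The other 23 of the 29 genes on that list were not listed. Mast cell genes were 3 higher and 4 lower (median log2 change -1.76, percentile 0.1 of the random lists), with Srgn (7.71), Ms4a2 (-6.93), Il1rl1 (-4.36) and Alox5ap (2.44). Globins were 2 higher and 0 lower, Hbb-b1 (4.66) and Hbb-b2 (2.81), and Hba-a1 (-0.24) was not listed. Glycolysis genes were 2 higher and 10 lower (median log2 change -1.64, percentile 0.1 of the random lists), with Slc2a3 (3.86), Pfkm (-2.33), Pdk1 (-1.93) and Ldha (-1.90). Red cell membrane genes were 5 higher and 4 lower (median log2 change 0.99, percentile 26.3 of the random lists), with Add2 (-3.66), Stom (-2.27), Kel (-2.16) and Ermap (1.77). Their median turned from 0.99 to -0.19 when centred on the median of all listed genes, a value that follows from the 2-fold filter. Other erythroid maturation genes were 6 higher and 2 lower (median log2 change 1.44, percentile 84.6 of the random lists), with Car1 (-4.46), Fam46c (2.85), Ube2l6 (1.99) and Bcl2l1 (1.85). Erythroid transcription factors were 6 higher and 2 lower (median log2 change 1.21, percentile 70.3 of the random lists), with Cbfa2t3 (1.88), Mllt3 (1.74), Tal1 (1.58) and Gata1 (1.21). Stem and progenitor genes were 4 higher and 2 lower (median log2 change 1.11, percentile 73.3 of the random lists), with Meis1 (2.25), Csf2rb2 (1.70), Cd44 (-1.44) and Gata2 (-1.35), and their median turned from 1.11 to -0.07 with the same centring. Heme synthesis genes were 2 higher and 1 lower (median log2 change 1.63, percentile 76.6 of the random lists), with Alas2 (-3.50), Alad (2.36) and Abcb10 (1.63). Immediate early and stress genes were 4 higher and 0 lower (median log2 change 1.94, percentile 87.3 of the random lists), with Zfp36 (3.06) and Jun (2.24). Iron handling genes were 1 higher and 2 lower (median log2 change -1.40, percentile 5.5 of the random lists), with Fth1 (-1.85) and Tfrc (-1.40), and cell cycle genes 5 higher and 1 lower (median log2 change 1.44, percentile 62.9 of the random lists), with Ccnd1 (4.01) and Ccnd3 (2.76). With 3 reads in GATA-1 2RA, the ratio and 95% counting interval were Alas2 16.2-fold (5.40 to 81.3).

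The authors' deposited table lists 805 genes between the mutants, 466 higher and 339 lower in GATA-1 2RA. With assumed BCVs of 0.2 and 0.4 these became 252 and 149, and 45 and 32.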

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

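All tests in this part were chosen after the results were seen. Some genes were listed in opposite directions against the G1E control: 39 between GATA-1 V205M and GATA-1 2RA, 40 between GATA-1 WT and GATA-1 V205M, and 29 between GATA-1 WT and GATA-1 2RA. Independent lists of these sizes would give 37.1, 65.4 and 58.0. Simulated unchanged groups that share the control's reads gave 0 for each of these pairs at a BCV of 0.05 and of 0.2, and 21, 31 and 34 at 0.4. Their genes were called by the same rule that assumed a BCV of 0.05, so these counts depend on that rule too. None of these differences between groups was tested, since each group is 1 sample.

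Of the genes named in the report, 11 were of this kind between the mutants, each given as the log2 change in GATA-1 V205M and then in GATA-1 2RA. Higher only in GATA-1 2RA were Cited1 (-4.93 and 1.57), Col18a1 (-4.18 and 3.53), Cpz (-3.10 and 2.29), Hbb-b1 (-1.37 and 3.29), P2rx1 (-2.62 and 1.98), Plek (-3.59 and 2.47) and Srgn (-3.78 and 3.93). Higher only in GATA-1 V205M were Ednra (3.32 and -5.42), Ggta1 (3.04 and -3.02), Il1rl1 (2.43 and -1.93) and Ms4a2 (1.45 and -5.49). These opposite directions were not tested.

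Among genes higher in GATA-1 WT than in the control, 577 were lower in a mutant than in GATA-1 WT. Gata1 RNA was lower in both mutants than in GATA-1 WT, and lowest of the 3 in GATA-1 V205M, so a lower amount of Gata1 RNA may contribute. If it set these genes' levels alone, those listed between the mutants should be higher in GATA-1 2RA, yet 53 of 153 (34.6%) were lower there. Of all 805 genes listed between the mutants, 339 were lower in GATA-1 2RA, so lower genes were common beyond this pattern too. The spread between cultures was not measured either. The share therefore cannot decide for or against the Gata1 order, and this stays open. The GATA-1 form and any other difference between the cell lines cannot be told apart with 1 sample per group.

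Hba-a1 and Hba-a2 were higher in the G1E control than in both mutants. Reads of GATA-1 WT in the control library would bring all abundant GATA-1 WT transcripts at 1 share, but of 178 genes with 1000 or more scaled reads there, 6 (Alas2, Btg2, Cldn13, Hbb-b1, Hbb-b2 and Slc2a3) lay below the share of Hba-a2. That share was 2.25% (95% counting interval 1.81 to 2.78) for Hba-a2 and 0.641% for Hbb-b1, which argues against such reads as the whole source. A different split of reads between the 2 copies is also excluded, because their sum was 23.7-fold higher in the control than in GATA-1 V205M (95% counting interval 19.8 to 28.3) and 33.6-fold higher than in GATA-1 2RA. A difference between the GATA-1 forms or between cultures remains open and was not tested.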

How the results depend on the processing

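The edgeR fits, the stricter adjusted p of 0.001 and the left-out count columns were chosen after seeing the data, and the other alternatives before. Of the counts under alternatives, 178 stayed within 1.5 times the reported count and 58 did not. List medians moved little in 273 cases, moved further in 84 and turned in 3, and 1668 values of single genes kept their direction and stayed within counting error. For genes with few reads this tolerance is wide. In GATA-1 WT vs G1E control, the standard error from counting was 1.449 on the log2 scale for Cited1. An adjusted p of at most 0.01 moves nothing, because the authors' threshold is already 0.01. Matching by symbol and locus together was not run, since the tables used hold no locus. Leaving out 1 of 2 count columns kept between 90.6% and 97.8% of the listed genes 2-fold apart in the same direction. No paired analysis was possible because the results come from no test of replicates and there is 1 sample per group. Depth limits the ratios of genes with few reads, and spread between cultures was not measured. With a 4-fold threshold, which keeps fewer genes by construction, the numbers of higher and lower genes were 348 and 242 in GATA-1 WT vs G1E control, 155 and 170 in GATA-1 V205M vs G1E control, 197 and 113 in GATA-1 2RA vs G1E control, 153 and 232 in GATA-1 V205M vs GATA-1 WT, 210 and 153 in GATA-1 2RA vs GATA-1 WT and 189 and 115 in GATA-1 2RA vs GATA-1 V205M. Genes listed in the same and in opposite directions against the control at 4-fold numbered 127 and 14 for GATA-1 WT and GATA-1 V205M, 127 and 8 for GATA-1 WT and GATA-1 2RA and 99 and 9 for GATA-1 V205M and GATA-1 2RA. Of genes higher in GATA-1 WT, 66 were then also higher in GATA-1 V205M and 133 short of GATA-1 WT, and of the lower genes 61 and 78. Of genes higher in GATA-1 WT, 81 were then also higher in GATA-1 2RA and 83 short of GATA-1 WT, and of the lower genes 46 and 92. With an edgeR exact test at an assumed BCV of 0.2, the higher and lower genes numbered 609 and 379 in GATA-1 WT vs G1E control, 234 and 241 in GATA-1 V205M vs G1E control, 268 and 149 in GATA-1 2RA vs G1E control, 218 and 385 in GATA-1 V205M vs GATA-1 WT, 254 and 257 in GATA-1 2RA vs GATA-1 WT and 252 and 149 in GATA-1 2RA vs GATA-1 V205M. At an assumed BCV of 0.4 these numbers were 60 and 46 in GATA-1 WT vs G1E control, 11 and 18 in GATA-1 V205M vs G1E control, 31 and 28 in GATA-1 2RA vs G1E control, 36 and 47 in GATA-1 V205M vs GATA-1 WT, 45 and 43 in GATA-1 2RA vs GATA-1 WT and 45 and 32 in GATA-1 2RA vs GATA-1 V205M. A joint edgeR quasi-likelihood fit used all 6 count columns for the 4 samples, so its common BCV of 0.0518 comes from columns that may be runs of 1 sample. It covered only genes with a level in all 4 groups and called every listed gene it covered, 871 of 871 in GATA-1 WT vs G1E control, so it sorted out none. The counts were 560 higher and 311 lower in GATA-1 WT vs G1E control, 361 higher and 261 lower in GATA-1 V205M vs G1E control, 435 higher and 214 lower in GATA-1 2RA vs G1E control, 276 higher and 443 lower in GATA-1 V205M vs GATA-1 WT, 310 higher and 361 lower in GATA-1 2RA vs GATA-1 WT and 318 higher and 212 lower in GATA-1 2RA vs GATA-1 V205M.

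Centring on the median of all listed genes shifts every change of a table by 1 value, by construction, and moved these list medians by more than counting error. Only changes above 2-fold are listed, so this value takes the sign of the direction with more listed genes. It measures no shift between libraries, and the medians that it moved or turned follow from the filter. In GATA-1 WT vs G1E control, with a median of 1.23, the new values were globins 4.22, heme synthesis 1.02, iron handling 0.54, red cell membrane 1.29, other maturation 1.04, erythroid factors 0.36, stem and progenitor -4.18, megakaryocyte -1.72, cell cycle 0.43, growth arrest 1.11, autophagy 0.44, immediate early 0.79, glycolysis 0.79, cholesterol -2.54, histones 0.22 and mitochondrially encoded -2.86. In GATA-1 V205M vs G1E control, with a median of 1.11, the new values were globins -2.69, heme synthesis 0.48, iron handling -0.10, red cell membrane -2.41, other maturation -2.70, erythroid factors 0.05, stem and progenitor 0.48, megakaryocyte -3.72, mast cell -3.05, cell cycle -1.26, growth arrest 0.62, immediate early 0.67, glycolysis 0.50, cholesterol -2.64, histones -2.27 and mitochondrially encoded -2.51. In GATA-1 2RA vs G1E control, with a median of 1.23, the new values were globins -1.63, heme synthesis 0.43, iron handling -2.66, red cell membrane -2.39, other maturation 0.14, erythroid factors 0.55, stem and progenitor 2.64, megakaryocyte 1.24, cell cycle 0.26, growth arrest 0.12, immediate early 1.41, glycolysis 0.33, cholesterol -2.98, histones -2.34 and mitochondrially encoded -2.32. In GATA-1 V205M vs GATA-1 WT, with a median of -1.16, the new values were globins -6.59, heme synthesis -1.57, iron handling -0.49, red cell membrane -2.16, other maturation -0.72, erythroid factors -0.53, stem and progenitor 3.48, cell cycle -0.48, growth arrest -0.88, autophagy -0.06, immediate early -0.62, glycolysis -1.61, cholesterol -0.27 and histones -0.06. In GATA-1 2RA vs GATA-1 WT, with a median of -1.07, the new values were globins -5.50, heme synthesis -0.37, iron handling -0.84, red cell membrane -1.69, other maturation -1.51, erythroid factors -0.39, stem and progenitor 4.36, megakaryocyte 3.01, mast cell 4.65, cell cycle -0.18, growth arrest -1.35, autophagy -1.21, glycolysis -0.80, cholesterol -0.31 and histones -0.12. In GATA-1 2RA vs GATA-1 V205M, with a median of 1.18, the new values were heme synthesis 0.45, iron handling -2.58, red cell membrane -0.19, other maturation 0.26, erythroid factors 0.02, stem and progenitor -0.07, megakaryocyte 1.81, mast cell -2.94, cell cycle 0.26, immediate early 0.76 and glycolysis -2.82. Of these, iron handling in GATA-1 V205M vs G1E control, and red cell membrane and stem and progenitor genes in GATA-1 2RA vs GATA-1 V205M, changed sign.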

Other observations

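Genes were also sorted by whether 1 group stood apart from the other 3 in all of its tables. G1E control was higher than every other group for 83 genes and lower for 176, GATA-1 WT for 227 and 122, GATA-1 2RA for 101 and 42, and GATA-1 V205M for 73 and 70. These counts share libraries across tables and were not tested.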
